A study of Mus musculus with 4 samples.

How the data were processed

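The study profiled binding of PLZF, the BTB zinc finger transcription factor encoded by Zbtb16, in mouse thymocytes on a C57BL/6 background. PLZF-DNA complexes were pulled down on streptavidin beads from sonicated nuclei of mice that carried a PLZF transgene and a transgene for BirA, the bacterial biotin ligase. Of the 4 samples, 2 were streptavidin ChIP libraries and 2 were input libraries. The ChIP library labelled Tg thy came from thymocytes of PLZF/BirA transgenic mice and is called the PLZF-transgenic library here. The ChIP library labelled NKT came from mice that also carried a Valpha14 transgene, the T cell receptor alpha chain of invariant natural killer T cells, and is called the NKT library; its cell type is given as thymocytes, without a word on sorting. Each group had 1 library, so no replicate error could be had, and the input libraries were not analysed here. No streptavidin pull-down from mice without the PLZF transgene was among the samples, so nonspecific signal cannot be told apart from PLZF binding.

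The deposited files were peak lists, 1 per ChIP library, with 5 columns and no header (chromosome, start, end, a peak name beginning with MACS, and a value). The fifth column was treated as a score that the authors deposited with each peak. Peak lists of this layout from early versions of MACS carry -10 times the log10 of the p-value in that column, and the lowest deposited values, 50.03 and 50.02, would then stand for a p near 1e-05, but neither the file nor the labels state this. Such a score grows with sequencing depth, and no read count was used here, so the depth is unknown. Scores were used to rank and filter peaks within a list. Scores of both lists given side by side describe each library and show no change between them. Per the submitters' processing notes, the tools were Bowtie, Picard and HOMER and the build was mm10. Versions, and whether the input libraries served as the control for peak calling, are not given in the sources used here. Each list belongs to 1 sample, and whether any reads were pooled before peak calling is not given in the sources used here. Starts were raised by 1 base to give 1-based coordinates.

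Gene names, spans and biotypes came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. The table holds no strand, exons or sequence. This changed the design from what was fixed before the data were examined. Distances were measured to the gene (0 inside it) or to either of its boundaries instead of to transcription start sites. Exon and UTR classes were not used. The alternative of gene bodies with 5 kb upstream became gene bodies with 5 kb on both sides, and assembly gaps were not left out of random placement. The planned motif test, with its 3 alternatives, was not run.

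A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Random expectation came from 1000 placements of each peak on its own chromosome, between the first and the last annotated gene or peak, since assembly gaps were not known. One-sided permutation p-values came from these placements, and 0.001 is the smallest they can give. Each nuclear peak midpoint was assigned to the nearest protein-coding gene within 100 kb, and to the gene with the closest boundary where it lay in several. Of 21883 protein-coding nuclear genes, those with at least 1 assigned peak were counted. For the list test, 13 gene lists, fixed before the data were examined, were tested for the number of genes with a peak against 100000 random gene lists matched on 10 classes of gene domain length, with one-sided permutation p-values (smallest possible 1e-05) and Benjamini-Hochberg adjustment over the 13 lists of a library at 0.05. The domain of a gene was its body plus the part of the gap to each neighbour that lies nearer to it, up to 100 kb a side. Of the 384 symbols in these lists and in the list of transgene loci below, 1 was not in the gene table, and Zfp683 is a pseudogene there and was left out. A list of loci whose sequence the transgenes may carry was described and not tested. These tests describe the 2 libraries and not the conditions, and no p-value was computed between the libraries. Exact (Clopper-Pearson) 95% intervals of shares cover counting error only, and peaks are not biological replicates.

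Regions were named by rule: the 10 peaks with the highest score in each list and the 5 highest among peaks that were not shared. Genes were named by rule as up to 4 genes per list with a peak in both libraries, ranked by NKT score, up to 2 with a peak in only 1 library, the 5 genes with the most peaks per library (with genes tied with the last of them, added after seeing the data), and all loci of the transgene list. Some genes that this rule names are not reported here. Alternatives were reciprocal 50% overlap (100 placements), midpoints within 1 kb, the top 50% or the top 1000 of each list by score, a 2.5 kb boundary window, protein-coding boundaries only, a 10 kb limit for the nearest gene, gene bodies with 5 kb on both sides, and unmatched random lists. Chosen after seeing the data were 2 more, namely leaving out the mitochondrial genome, the Y chromosome and 6 regions taken to be repeat-rich from their clustered or isolated peaks (no sequence was read) and using shared peaks only in the list test. For the description by score, each list was divided into 10 score classes of nearly equal size.

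The procedures were tested on simulated data. Of 200 peaks planted in both simulated lists, 200 were found as overlapping. With the nuclear NKT peaks placed at random 20 times and 5000 random lists per test, 6 of the 20 sets gave a list call without any effect, more than the threshold of 0.05 aims at. Of these, 4 were for the neuronal list, whose genes are long. A planted list with 16 of its genes given a peak was called in 20 of 20 sets. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.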

Results

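Streptavidin ChIP peaks, meant to mark PLZF, were listed for 2 thymocyte populations. With no control pull-down from mice lacking the PLZF transgene, a peak here need not be a PLZF site. The populations came from PLZF-transgenic mice and from mice that carried the Valpha14 T cell receptor transgene as well, which the labels call NKT. The labels give thymocytes as the cell type of both and do not say whether natural killer T cells were sorted, so NKT names the library here and not a cell type. PLZF is the factor that directs the innate-like effector program of natural killer T cells. The PLZF-transgenic list held 5198 peaks that covered 2345 kb, with a median width of 387 bp (quartiles 293 to 540 bp). The NKT list held 4246 narrower peaks that covered 1256 kb, with a median width of 224 bp (quartiles 171 to 337 bp). The median peak score was 110.8 in the PLZF-transgenic list and 73.8 in the NKT list. There was 1 library per group and no replicate, and the depth of the libraries is unknown, so neither difference has a replicate check and intervals below cover counting error only.

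The first comparison asked whether peaks lay at the same places in both populations. The strongest sites were common to both lists. Besides mitochondrial DNA, the highest-scoring PLZF-transgenic peaks lay 2.18 kb from Sag on chromosome 1 (87846642 to 87848032, score 3133, and 3100.0 in the NKT list), 13.8 kb from Spats1 on chromosome 17 (45488045 to 45489730, 3102, and 1455 in NKT) and inside Gpr132 and the noncoding gene Gm30461 on chromosome 12 (112860657 to 112862455, 3100.0). The NKT list divided this Gpr132 site into a pair of peaks with scores of 3104 and 2773. Gpr132 encodes a G protein-coupled receptor of lymphocytes and macrophages. Peaks inside Cog3 on chromosome 14 (75710039 to 75711624), Metap1d on chromosome 2 (71485825 to 71487051) and Xrcc6 on chromosome 15 (82027366 to 82028575) had scores of 3100.0, 3100.0 and 2785 in the PLZF-transgenic list and of 1912, 1679 and 1793 in the NKT list. Xrcc6 encodes the DNA repair protein Ku70. The score of exactly 3100.0 recurred at unrelated sites in both lists, with few values above it. It may be a ceiling of the score, so the order of these sites and their score pairs should not be read as exact. A PLZF-transgenic peak of score 3100.0 on chromosome 6 (41552791 to 41555102) lay within the T cell receptor beta locus Tcrb, where the NKT list had several overlapping peaks, the highest with scores of 854.8 and 842.1. Among the 10 highest NKT scores were also a site inside the noncoding gene Gm40841 on chromosome 13 (28417328 to 28418579, score 2031, and 2605 in the PLZF-transgenic list), 266.4 kb from the nearest protein-coding gene, and a site 3.26 kb from the noncoding gene AY036118 on chromosome 17 (39842908 to 39846789, score 1809, and 71.3 in the PLZF-transgenic list). The site near AY036118 lies in a region presumed to be repeat-rich.

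Of the NKT peaks, 2579 of 4246 overlapped a PLZF-transgenic peak, 60.7% (exact 95% interval 59.3 to 62.2%). Of the PLZF-transgenic peaks, 2374 of 5198 overlapped an NKT peak, 45.7% (44.3 to 47.0%). Random placement gave a mean of 10.6 and 11.3 overlapping peaks (one-sided permutation p = 0.001 for each, the smallest possible). Without the mitochondrial genome, the Y chromosome and the presumed repeat-rich regions the means were 6.69 and 6.64. Placement was even along each chromosome, so the test cannot tell common PLZF sites from a common preference for some kinds of region. The share rose with the peak score. In the highest of 10 score classes, 98.1% of NKT peaks (96.3 to 99.2%) and 96.7% of PLZF-transgenic peaks (94.8 to 98.1%) were shared. In the lowest class, 29.9% (25.6 to 34.5%) and 15.8% (12.7 to 19.2%) were shared. Requiring both peaks to overlap by 50% of their length lowered the shares to 36.5% and 29.8%. Across the 2374 overlapping pairs, scores correlated with a Spearman rho of 0.61. This is a correlation across peaks, which are not independent replicates. The PLZF-transgenic peak was the wider one in 90.5% of pairs and the higher-scoring one in 80.8%, values that can move with the unknown depth of the libraries.

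**Figure D1:**
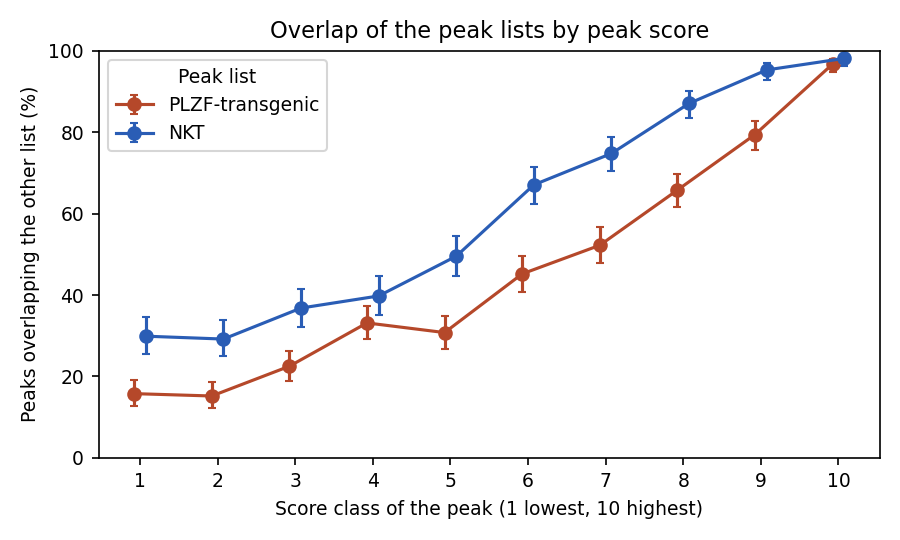
Percent of peaks of each list that overlap the other list by at least 1 bp (vertical axis) for each of 10 classes of the list by peak score (horizontal axis); points are shares and bars exact 95% binomial intervals. The share rises from 15.8% to 96.7% in the PLZF-transgenic list and from 29.9% to 98.1% in the NKT list.

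Peaks listed in 1 library only numbered 2824 in the PLZF-transgenic list and 1667 in the NKT list. Their median scores were 83.8 and 57.8, against 190.2 and 103.5 for shared peaks. Outside mitochondrial DNA, the highest-scoring unshared PLZF-transgenic peaks lay 89.5 kb from Tnfaip3 (chromosome 10, 19104534 to 19105286, score 661.9), 26.1 kb from Dusp10 (chromosome 1, 184101199 to 184102175, 572.6), inside Hvcn1 (chromosome 5, 122234487 to 122235480, 474.4) and 12.8 kb from Fmod (chromosome 1, 134060715 to 134061410, 460.8). Tnfaip3 encodes A20, an inhibitor of NF-kB signalling, and Dusp10 a phosphatase of MAP kinases. The highest-scoring unshared NKT peaks lay inside Sfi1 (chromosome 11, 3191043 to 3195259, 491.2), inside the noncoding genes Gm34259 (chromosome 17, 4626212 to 4626639, 434.3) and D130079A08Rik (chromosome 14, 104336949 to 104337102, 282.1), and at a pair of places about 1 Mb from the nearest protein-coding gene on chromosome 2 (98666204 to 98667363, 488.4, and 98662203 to 98663001, 337.8). The Sfi1 peak and both chromosome 2 peaks lie in regions presumed to be repeat-rich.

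Where peaks lay relative to genes differed little between the lists. Within 1 kb of a gene boundary were 25.4% of nuclear PLZF-transgenic peaks (24.2 to 26.6%) and 26.3% of NKT peaks (24.9 to 27.6%), against 6.46% and 6.47% of randomly placed peaks (one-sided permutation p = 0.001 for each, the smallest possible). Start and end of a gene were not told apart. A further 49.3% and 47.3% lay inside genes, where random placement put 45.2% and 45.1%. Between genes lay 25.4% and 26.4%, where random placement put 48.3% and 48.4%. Shared and unshared peaks had nearly equal shares near boundaries, 25.5% and 25.2% in the PLZF-transgenic list and 26.3% and 26.3% in the NKT list.

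The next comparison asked which genes lay next to peaks in each population. At least 1 peak was assigned to 2982 protein-coding genes in the PLZF-transgenic list and to 2562 in the NKT list, of 21883. Both lists held 1804 of them, where independent lists of these sizes would share 349.1. The PLZF-transgenic list alone held 1178 genes and the NKT list alone 758. The genes with the most peaks in the PLZF-transgenic list were Ets1 and Ppm1h with 12 each, then Ccnd3, Clec16a, Ldlrad3 and Runx1 with 11 each. In the NKT list, Sfi1 had 29, all within a region presumed to be repeat-rich, followed by Ets1 with 9 and by Ccnd3, Pde4d, Rhoh, Septin9, Tex14 and Trim33 with 8 each. These counts take no account of gene domain length, and long domains can collect more peaks. The domain was 391.5 kb for Ppm1h and 1450.9 kb for Pde4d, but 96.0 kb for Ccnd3 and 70.4 kb for Rhoh. Ets1 is an ETS family transcription factor of lymphocytes, Ccnd3 encodes cyclin D3, which thymocytes need to expand, and Rhoh a small GTPase of T cell receptor signalling.

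Genes of T cell receptor signalling held peaks most often among the lists tested. Of its 32 genes, 28 had a peak in the PLZF-transgenic list (5.55 times the mean of matched random lists) and 25 in the NKT list (5.62 times), and 24 had one in both. The adjusted permutation p was 3.25e-05 and 4.33e-05, from the smallest p the random lists can give, and over the alternatives the NKT value ranged from 5.33 times with gene bodies to 8.52 times with the top 50% of the peaks by score. High NKT scores belonged to Cd4 (1158, and 2245 in the PLZF-transgenic list), the CD8 beta chain gene Cd8b1 (706.9 and 667.8) and Cd3d (504.9 and 1043). Cd4, Lck and Cd2, all among the 24 genes with a peak in both, are also loci whose sequence the transgenes may carry. The only Cd4 peak was 9460 bp wide in the PLZF-transgenic list and 9171 bp in the NKT list, and transgene DNA stays open for it. The list test was not repeated without these genes. Sh2d1a, which encodes the adaptor SAP that natural killer T cells require, had a peak of score 136.5 in the NKT list and none in the PLZF-transgenic list. Ctla4 had 2 peaks in the PLZF-transgenic list, the higher with a score of 121.5, and none in the NKT list.

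Transcription factors of the T lineage had the next highest share of genes with a peak among the immune lists. A peak was assigned to 27 of 37 in the PLZF-transgenic list (3.97 times the random mean, adjusted permutation p = 3.25e-05) and to 23 in the NKT list (3.71 times, adjusted permutation p = 4.33e-05), with 21 in both. Tcf7, which encodes TCF1, had 7 PLZF-transgenic and 5 NKT peaks, the highest about 31 kb away with scores of 1760 and 831.4. Prdm1, which encodes BLIMP1, had 1 peak in each (688.5 and 469.4), as had Rora (548.6 and 338.4). Ets1 had highest scores of 862.2 inside the gene and 444.3 at a distance of 44.0 kb. By nearest gene, Eomes had a peak in the PLZF-transgenic list alone (246.7, 81.4 kb away) and Nfatc2 in the NKT list alone (111.7, inside the gene). Chosen after their values were seen, Bach2 had 3 peaks in the PLZF-transgenic list, the highest of score 99.5, and none in the NKT list, and Tbx21, Zbtb7b, Maf, Id2 and Id3 had no assigned peak in either.

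Migration and adhesion genes had peaks at 14 of 29 in each list, 13 of them in both (3.52 and 4.11 times the random mean, adjusted permutation p = 6.5e-05 and 4.33e-05). Over the alternatives the PLZF-transgenic value ranged from 2.48 times with gene bodies to 6.01 times with shared peaks only, and the NKT value from 3.37 times with gene bodies to 6.68 times with the top 50% of the peaks by score. The chemokine receptor gene Ccr9 had scores of 977.1 in the PLZF-transgenic and 495.5 in the NKT list (10.4 and 12.6 kb away), Selplg (the P-selectin ligand) 854.4 and 445.3, and Cd69 782.8 and 274.2. By nearest gene, Icam2 had peaks in the PLZF-transgenic list alone (94.1), although 1 NKT peak overlapped its body with 5 kb on both sides. Klf2, which encodes a regulator of thymic exit, had a peak in the NKT list alone (81.2). Effector genes of innate-like T cells had peaks at 17 of 36 in the PLZF-transgenic list (3.32 times, adjusted permutation p = 3.25e-05) and at 11 in the NKT list (2.54 times, adjusted permutation p = 0.00561), and all 11 were among the 17. The highest NKT scores were those of Il4ra (359.1, and 412.7 in the PLZF-transgenic list), Tnfsf11 (247.0 and 694.6, 48.8 and 48.7 kb away), Ifngr1 (182.5 inside the gene and 328.0 at 93.6 kb) and Il2ra (138.5 and 511.8). Apart from Tnfsf11, which encodes the cytokine RANKL, these are cytokine receptor genes. Slamf1 (263.1) and Il18r1 (96.7) had peaks in the PLZF-transgenic list alone. The cytokine genes Il4, Il13 and Ifng, chosen after their values were seen, had no assigned peak in either list.

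Survival and apoptosis genes had peaks at 13 of 25 in the PLZF-transgenic list (3.69 times, adjusted permutation p = 6.5e-05) and 10 in the NKT list (3.35 times, adjusted permutation p = 0.000806). Tnfrsf1a had scores of 528.8 and 399.8, Traf2 762.3 and 259.2, Tnfaip3 772.4 and 165.1 (47.2 and 47.1 kb away), and Pim1 232.5 and 104.2, the PLZF-transgenic value first. Tnfrsf1b (183.3) and Birc3 (89.8) had peaks in the PLZF-transgenic list alone. Co-repressor and chromatin genes passed the threshold in the PLZF-transgenic list, with 10 of 26 (2.42 times, adjusted permutation p = 0.00743), and missed it in the NKT list, with 7 (1.92 times, adjusted permutation p = 0.109). Among them, Hdac7 had scores of 674.5 and 845.0, Hdac4 229.0 and 170.0, Smarca4 361.7 and 112.9, and Rcor1 94.3 and 81.5. Cul3, which encodes a ubiquitin ligase scaffold that binds PLZF, had a peak of score 116.6 at a distance of 72.0 kb and Sin3b one of 108.2 inside the gene, both in the PLZF-transgenic list alone. Cell cycle genes likewise passed with 9 of 29 (2.40 times, adjusted permutation p = 0.0134) and missed it with 6 (1.93 times, adjusted permutation p = 0.131). Ccnd3 had scores of 1216 and 321.3, E2f3 529.8 and 235.1, E2f1 119.4 and 119.6, and E2f2 153.3 and 94.98. Cdkn1a (121.3) had peaks in the NKT list alone and Aurkb (109.0) in the PLZF-transgenic list alone. The difference between the libraries was not tested for either list. Both PLZF-transgenic calls ended with the top 50% of the peaks by score. The co-repressor list was then at 2.03 times (adjusted permutation p = 0.146, range over alternatives 0.00154 to 0.6). The cell cycle list was at 2.36 times (adjusted permutation p = 0.101, range 0.0133 to 0.101). With the top 50% of the peaks the NKT cell cycle list passed (3.38 times, adjusted permutation p = 0.014, range 0.014 to 0.189). Of 20 simulated sets without any effect, 6 gave a list call, 4 of them for the neuronal list. The adjusted p-values of the list tests may thus be too small.

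Ribosomal protein genes, active in all cells, also had peaks more often than matched genes, at 16 of 41 in the PLZF-transgenic list (4.58 times, adjusted permutation p = 3.25e-05) and 11 in the NKT list (3.96 times, adjusted permutation p = 0.000162). Rpl3 had scores of 440.9 and 215.3, Rpl27 180.8 and 187.0, Rpl14 233.1 and 137.6, and Rpl32 169.3 and 70.9, the PLZF-transgenic value first, and Rps7 (103.1) had a peak in the PLZF-transgenic list alone. With random lists not matched on gene domain length the values were 2.86 and 2.29 times (adjusted permutation p = 0.000173 and 0.0138). The NKT call ended with the top 50% of the peaks by score (2.03 times, adjusted permutation p = 0.298, range over alternatives 4.33e-05 to 0.298). Against matched lists, the ribosomal value was above the T lineage factor, effector and survival values in both libraries. It was below the T cell receptor signalling value in both and below the migration value in the NKT library. Against unmatched lists it was below all of these. Random lists were not matched on expression, so the calls of the T cell lists cannot be told apart from peaks at active genes in general.

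Marker genes of other cell types in the thymus did not pass. Of 20 B cell genes, 2 had a peak in the PLZF-transgenic list and 4 in the NKT list, where matched random lists gave 2.38 and 2.08 (adjusted permutation p = 0.927 and 0.206). Those in both were Cr2 (112.7 and 109.6, both 64.8 kb away) and Rag1 (475.6 and 93.1), and thymocytes also express Rag1. Pou2af1 (54.8) and Blk (50.2) were in the NKT list alone. Of 27 myeloid and dendritic genes, 4 and 2 had a peak against 3.69 and 3.04 at random (adjusted permutation p = 0.746 and 1.0), with Flt3 (295.7 and 149.1) and Itgam (223.2 and 139.2) in both and Cebpb (62.2, 85.2 kb away) and S100a9 (58.5, 14.5 kb away) in the PLZF-transgenic list alone. Of 24 thymic stroma genes, 0 and 1 had a peak against 3.41 and 2.90 at random, the 1 being Epcam (52.1, 65.0 kb away). No erythroid gene of 17 had one, where 1.97 and 1.66 were the random means. Of 30 neuronal genes, 3 and 1 had a peak against 5.51 and 5.08 at random, namely Nrxn3 in both (67.6 and 78.7) and Syn2 (159.3, 11.5 kb away) and Camk2a (53.1) in the PLZF-transgenic list alone. The adjusted permutation p of these 3 lists was 1.0 in both libraries. The test was one-sided and looked only for more genes with a peak than at random, so it does not speak to fewer.

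**Figure D2:**
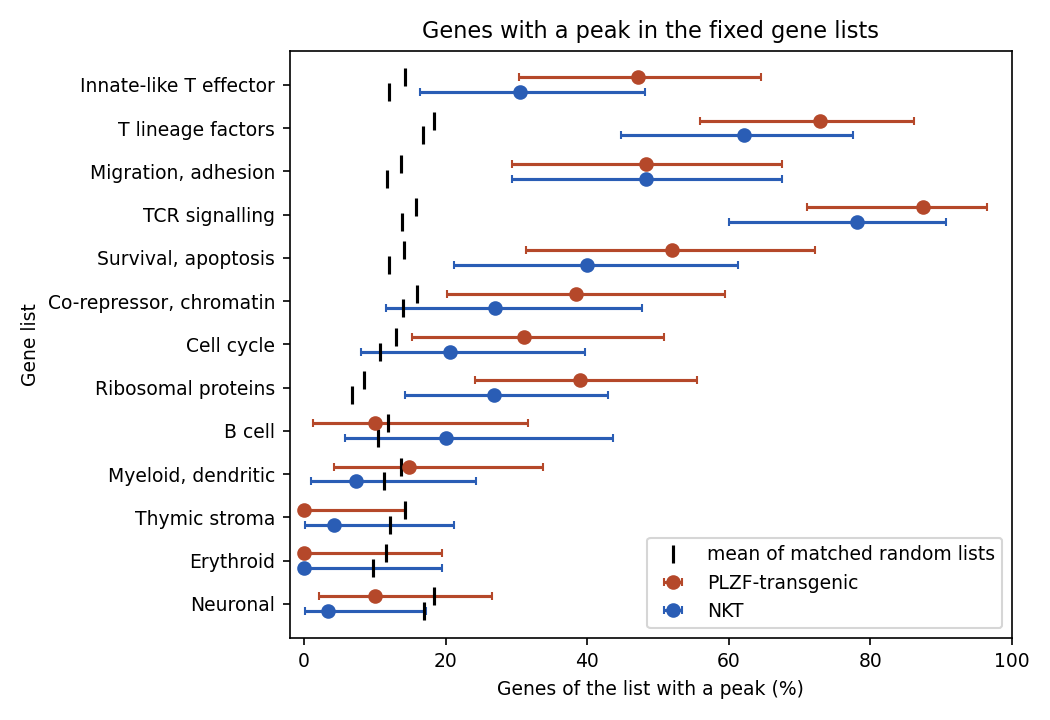
Percent of the genes of each fixed list (vertical axis) with an assigned peak (horizontal axis); points are shares with exact 95% binomial intervals, and black ticks the mean of random gene lists matched on gene domain length. T cell receptor signalling genes reach 87.5% in the PLZF-transgenic list and 78.1% in the NKT list, while erythroid genes are at 0 in both.

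Loci whose sequence may be present in the transgenes were read in both lists, whatever their values. Zbtb16, the gene of PLZF itself (chromosome 9, 48651797 to 48836225), had 6 peaks in the PLZF-transgenic list and 7 in the NKT list, all inside the gene, and 6 were common to both. The highest was 1469 bp wide with a score of 572.3 in the PLZF-transgenic list (48831632 to 48833100) and 1376 bp wide with 462.8 in the NKT list. The others were 193 to 437 bp wide. Cd4 (chromosome 6, 124864693 to 124888247) had 1 peak in each list, 9460 bp wide in the PLZF-transgenic list (124879303 to 124888762) and 9171 bp in the NKT list (124879561 to 124888731). Each was the widest nuclear peak of its list, followed by peaks of 5812 and 4624 bp. Within 5 kb of Lck were 3 PLZF-transgenic peaks and 1 NKT peak (highest scores 177.7 and 126.6), and within 5 kb of Cd2 were 2 in each (309.6 and 151.3). Within 5 kb of the T cell receptor alpha constant gene Trac were 2 PLZF-transgenic and 3 NKT peaks (1482 and 721.1). The Rosa26 locus and the gene segments Trav11, Trav11d and Traj18, which form the Valpha14-Jalpha18 chain, had no peak within 5 kb in either list.

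**Figure D3:**
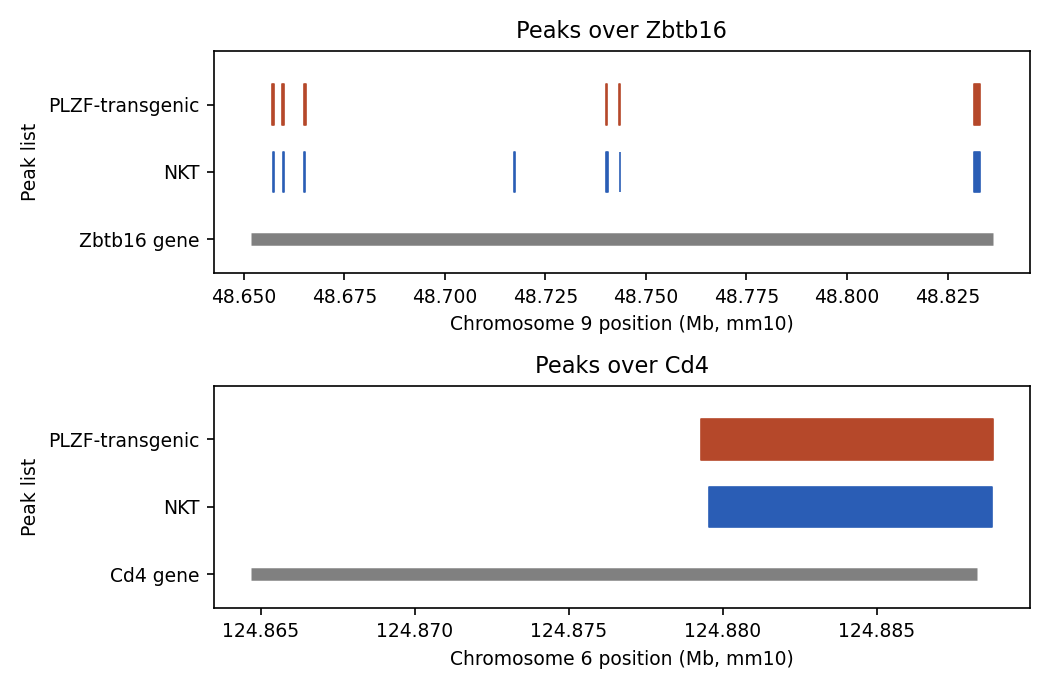
Peaks of both lists (coloured blocks, drawn to scale) over the annotated span of Zbtb16 and of Cd4 (grey), with position in Mb of mm10 on the horizontal axis and the list on the vertical axis. Zbtb16 holds 6 narrow or moderately wide peaks at the same places in both lists and 1 more in the NKT list. The Cd4 peaks are 9460 and 9171 bp wide and reach past the gene boundary at the higher coordinate, with strand not read.

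Peaks were unevenly spread over the chromosomes. Autosomes held 2.12 peaks per Mb in the PLZF-transgenic list and 1.72 in the NKT list, from 1.39 and 1.16 on chromosome 18 to 4.08 and 3.39 on chromosome 11. The X chromosome held 23 and 28 peaks, 0.135 and 0.164 per Mb, which was 15.7 and 10.5 times below the autosomal density. Per protein-coding gene the autosomes exceeded the X chromosome by 10.5 and 7.03 times. Neither copy number nor mappability of the X chromosome was taken into account. The cause was not tested, so the low density does not show that PLZF avoids this chromosome. The regions presumed to be repeat-rich were chosen after their values were seen. In 1 of them, the part of chromosome 11 from 3000000 to 3300000, around Sfi1, there were 29 NKT and 8 PLZF-transgenic peaks that covered 44986 and 19311 bp. The region near AY036118 on chromosome 17 held 2 peaks in each list, with scores up to 1809 in the NKT and 325.9 in the PLZF-transgenic list.

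**Figure D4:**
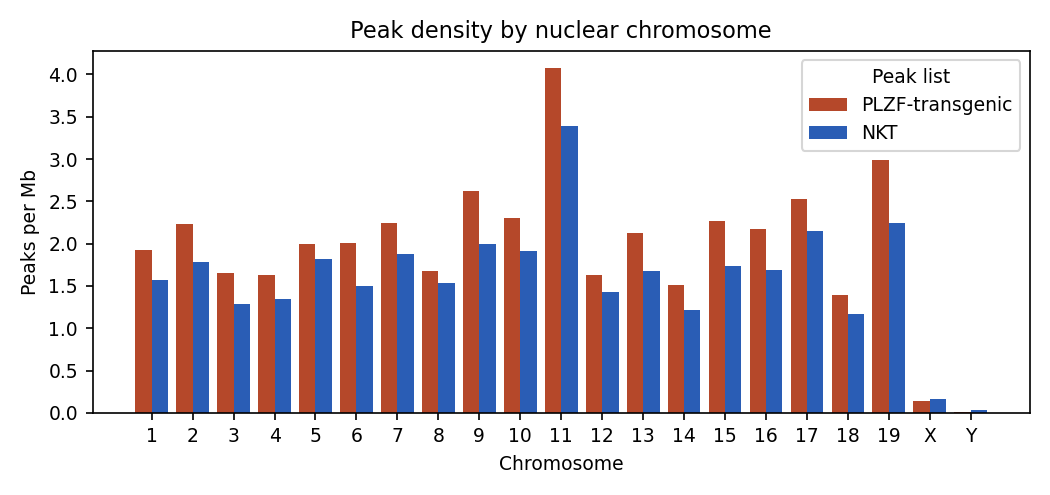
Peaks per Mb (vertical axis, bars from 0) on each nuclear chromosome (horizontal axis) for both lists. Chromosome 11 has the highest density, 4.08 and 3.39 per Mb, and the X chromosome lies far below every autosome.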

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

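All tests in this part except the one on shifted peak boundaries were chosen after the result was seen. The mitochondrial genome, which no gene comparison used, held 6 peaks in the PLZF-transgenic list and 4 in the NKT list. They covered 68.4% and 60.95% of the mitochondrial span, against 0.0864% and 0.0461% of the nuclear spans. Carry-over of mitochondrial DNA, which is present in many copies per cell, is a candidate explanation that would give such coverage, but it was drawn from these same peaks and stays open. No biological explanation was tested, and the input libraries, which would show the same DNA without pull-down, were not analysed here.

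The peaks listed in 1 library only form the second pattern. Of the unshared peaks, 9.84% in the PLZF-transgenic list and 11.52% in the NKT list had a peak of the other list within 1 kb, which leaves shifted peak boundaries open for a part of them. The calling threshold and depth are a candidate explanation too, under which strong peaks should be nearly all shared; in the highest of 10 score classes the lower of the shares was 96.73%, but this rise with score was the observation that prompted the explanation and does not test it. Of the 17 unshared peaks in the highest class of the PLZF-transgenic list 1 was mitochondrial, and of the 8 in that of the NKT list 5 lay in presumed repeat-rich regions, which leaves 16 and 3. Those regions were picked from these same peak lists, so this count is no separate evidence on what the unshared peaks are. A difference between the cell populations stays open and untested, and with 1 library each it cannot be told apart from a difference between the libraries.

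The third pattern is the set of peaks over Zbtb16 with the broad peak over Cd4. The Cd4 peak was 24.4 and 40.9 times the median width of its list. It was at least 2.362 times as wide as any of the 8 and 14 other nuclear peaks of the same or a higher score. This argues against a single focal binding site there, although the width was what drew attention to the peak, so it is no independent test. A broad bound or open region and transgene DNA stay open. Transgene DNA carried in the libraries is a candidate explanation for the Zbtb16 peaks, since both strains carry a PLZF transgene. All 6 PLZF-transgenic peaks and 85.71% of the NKT peaks over Zbtb16 were found in the other list, where peaks of like score were shared at 54.9% and 80.2%, so the PLZF-transgenic value lies above that of other peaks and the NKT value close to it, on few peaks. Binding at the endogenous gene would give shared peaks too, and without exons to set beside the peaks the 2 cannot be told apart.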

How the results depend on the processing

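All but 2 of the alternatives were fixed before the data were examined, with gene boundaries since put in place of start sites and 5 kb on both sides in place of upstream. The exceptions were the removal of mitochondrial, Y and presumed repeat-rich regions and the use of shared peaks only. The overlap of the lists, the share near gene boundaries and the number of gene lists past the threshold kept their direction and side of the threshold, or stayed within 1.5 times, under each alternative run. The shared percentage ranged from 29.8 to 63.6 for PLZF-transgenic peaks and from 36.5 to 70.0 for NKT peaks, lowest with reciprocal 50% overlap, and was 45.6 and 61.2 without the repeat-rich regions. The share near boundaries was highest with a 2.5 kb window (37.1% and 37.6%). With the top 50% of each list by score, the genes with a peak fell to 1714 in the PLZF-transgenic list, 1457 in the NKT list and 1111 in both, as follows from fewer peaks. The gene lists past the threshold were 6 to 8 in the PLZF-transgenic library and 6 or 7 in the NKT library. The T cell receptor signalling, T lineage factor, migration, effector and survival lists passed in both libraries under every alternative run. Besides the calls lost with the top 50% of the peaks, the co-repressor and cell cycle calls of the PLZF-transgenic library ended with shared peaks only (1.28 and 2.51 times, adjusted permutation p = 0.6 and 0.0815). In the NKT library the co-repressor list passed with unmatched random lists (2.30 times, adjusted permutation p = 0.0476, range over alternatives 0.0476 to 0.601) and the cell cycle list with the top 50% (3.38 times). Some lists that never passed changed side of the random mean. The B cell list in the PLZF-transgenic library, at 0.84 times, went to 1.14 with gene bodies, 1.499 with the top 50% and 1.54 with shared peaks. The myeloid list there, at 1.08 times, went to 0.64 within 10 kb, 0.62 with gene bodies and 0.95 with the top 50%, and in the NKT library, at 0.66 times, to 1.13 with the top 50% and 1.02 with shared peaks. The cause was not tested. The 3 motif alternatives were not run because no sequence was used here. No replicate could be left out, with 1 library per group, and unknown depth limits any comparison of peak numbers, widths and scores between the libraries.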

Other observations

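All tests in this part were chosen after the result was seen. The T cell receptor alpha and delta locus held more peaks than random placement gave. Within 100 kb of the alpha and delta gene segments on chromosome 14 (52427967 to 54224198) were 14 PLZF-transgenic and 13 NKT peaks, against 2.98 and 2.36 in random placements (one-sided permutation p = 0.001, the smallest possible, adjusted over 6 tests p = 0.003 in each). The highest lay just beyond the last segment at 54233086 to 54233954 with a score of 1503, and at 54233046 to 54234015 with 1032 in the NKT list, in the interval between Trac and Dad1. The beta locus on chromosome 6 (40891296 to 41558371) had 6 and 4 peaks against 1.73 and 1.30 (one-sided permutation p = 0.012 and 0.042, adjusted p = 0.024 and 0.0629), so the NKT value did not pass. The gamma locus on chromosome 13 had 1 PLZF-transgenic peak, of score 50.1, and 0 NKT peaks, against 0.799 and 0.636. Placement was even along each chromosome, while peaks in general lay near gene boundaries more often than random. The tests therefore cannot tell these loci from other stretches near genes. Adjustment over 6 tests does not cover the choice of the loci after seeing the data.

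The effector list was divided into genes of receptors and other surface molecules and genes of products, namely cytokines, chemokines, cytolytic proteins and TNF-family ligands. Of 21 receptor genes, 9 had a peak in both libraries, 42.9%, and of 15 product genes 2 had one, 13.3% (two-sided Fisher's exact p = 0.0769). For the PLZF-transgenic list by itself the counts were 13 and 4 (two-sided Fisher's exact p = 0.0489), without correction for several tests. Fisher's test took no account of gene length, and many of the product genes are much shorter than most of the receptor genes. Whether receptor genes hold peaks more often than product genes of like length may be worth testing on a larger list. This one is too short to decide.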
